A study of Mus musculus with 4 samples.

How the data were processed

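The samples were total RNA from testes of busulfan-treated male mice, 2 of Lhcgr knockout and 2 of control wild type. Per the labels' protocols, the RNA was converted to sense-strand cDNA, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, which read 1 colour. The deposited table gives 1 intensity per probe set and array on a linear scale. The submitters' processing notes name the genome build mm9. The summarization of probes, the background correction and the normalization behind the deposited intensities are not given in the sources used here. The lowest deposited intensity was just over 16 on each of the 4 arrays, as if 16 had been added to values near 0. Between 3 and 17 probe sets per array lay under 17 intensity units, and array medians ran from 198 to 215. If so, the added amount would compress the fold changes of weakly expressed genes, and folds of genes near the floor would understate the change. No detection calls were used here, so no gene was tested for being above background. After the data were seen, a named gene whose lower group mean lay among the weakest 5% of genes was given a lower bound in size, the lower end of the 95% confidence interval of its fold, which holds for 7 genes.

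Of the 28856 probe sets, 21789 have 1 gene symbol in the platform annotation, 1621 have several and 5446 have none listed. Probe sets with several or none were left out of the gene tests and are named for no gene. Symbols were checked through the Entrez number against a table of RefSeq genes on GRCm38.p6, in which 21698 of the 21789 matched, 91 did not and 0 symbols changed. That build differs from mm9, so it served only for names and for the order of neighbouring genes. The 21789 probe sets stand for 19938 genes. Where a gene had several probe sets, which holds for 999 genes, the one with the highest mean over the arrays was used.

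Values were taken to log2 and compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes under a constant prior and no covariates. The deposited values were linear rather than log2, and the log2 step followed the design as planned. P-values were two-sided and adjusted over the 19938 genes by the Benjamini-Hochberg method with a threshold of 0.05. Changes are given as log2 fold change, knockout over wild type, with the standard error after eBayes, over 2 arrays per group. The prior carried 4.65 degrees of freedom beside the 2 residual ones. Median centring or another scaling was not part of the main setting, and the median log2 fold change of all genes was 0.07.

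Before the data were examined, 30 gene lists with 642 different genes were written down from general knowledge, and 597 of these genes were measured. Camera tested each list with at least 5 measured genes against the other genes, with a preset inter-gene correlation of 0.01 and adjustment over 29 lists. The red blood cell list has 3 measured genes and was not tested. None of the 8 list calls holds with an estimated correlation. On simulated data without correlation between genes, a list of the same design was shifted by -0.8 on the log2 scale. There the preset correlation gave a camera adjusted p of 4.48e-46 and the estimated one 0.297. As the simulated genes were independent, this does not tell which setting suits lists whose genes vary together, and fry was not run on it. On simulated arrays with 200 changed genes, the gene test recovered 81% of the changes of 1 log2 unit and 99% of those of 2 log2 units among 19938 genes, with 4 unchanged genes called and 0 wrong signs. Each gene's variance there was drawn from limma's fitted prior, equal in both groups, with independent genes and no array effects. These rates hold under the test's own assumptions and do not measure its power or errors in the real data.

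The genes named were fixed by a rule written before the data were examined. It takes 12 preset genes whatever their values, the 10 largest changes in each direction among genes past the threshold, and in each list up to 4 members past the threshold with the largest change. Where no member passed, it takes the 2 with the lowest p. Unnamed loci, olfactory and vomeronasal receptors and small RNA genes were left out of the largest changes. Of the preset genes, Lhcgr, Insl3 and Rhox5 are not analysed here and 1 other is not reported here, and so the planned value for the targeted gene could not be computed.

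Alternatives set beforehand were quantile normalization, centring each array on its median, leaving out the lowest 25% or 50% of genes by mean, averaging a gene's probe sets, testing every probe set, eBayes with trend or with a robust prior, leaving out each array, the replicate number as a block, a fold threshold, a looser threshold of 0.1, and an ordinary pooled-variance test. For lists, these were camera with an estimated correlation, camera on ranks and fry. Adding a further 32 before the log2 step was chosen after seeing the data, as were a list of other acute-phase genes and a second list of epididymal genes. The labels give no array batch or scan date. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.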

Results

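Gene expression was measured in testes of mice treated with busulfan, an alkylating drug that removes most germ cells and leaves mainly the somatic cells of the testis. The mice lacked Lhcgr or were wild-type controls, and the tissue was taken 4 weeks after a dose of 44 mg/kg. Lhcgr encodes the receptor for luteinizing hormone, which drives testosterone synthesis in Leydig cells. Total RNA from 2 knockout and 2 wild-type samples was labelled with biotin and hybridised to 1-colour Affymetrix whole-transcript arrays. Each of the 4 arrays carried 28856 probe sets with a median between 198 and 215 intensity units, and 19938 genes entered the comparison. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

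The comparison asked how loss of the receptor changes gene expression in a testis depleted of germ cells, including the signals that somatic cells send to spermatogonial stem cells. In the knockout testes, 8 of 21 adult Leydig cell markers and 7 of 17 androgen-responsive genes of Sertoli cells fell, and Wnt5a, a secreted Wnt ligand, rose. As groups, both lists were lower than other genes in a test with a preset correlation, but had adjusted p = 0.616 with an estimated correlation. In all, 618 genes passed the test, 192 of them higher and 426 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05). Among these, 64 were at least 2-fold higher and 213 at least 2-fold lower, and 51 were at least 4-fold lower against 6 at least 4-fold higher. Values for the targeted gene Lhcgr are not analysed here, so the genotype labels were not checked on it. Values for Insl3 and Rhox5 are also not analysed here.

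Genes of steroid hormone synthesis were lower in the knockout. Hsd3b6 (probe set 10500559), a 3-beta-hydroxysteroid dehydrogenase of adult Leydig cells, fell from a mean of 12.27 ± 0.08 (SD, n = 2) to 5.46 ± 0.41 log2 intensity units. The knockout mean lies among the weakest 5% of genes, so the change is given as a lower bound, at least 81.1-fold, the lower end of its 95% confidence interval (limma adjusted p = 0.000119). The lower means of Sult1e1, Trpc5os, Ptgds, Ces1d, Cd36 and Tspan8 lie there too. By the same rule Sult1e1 was at least 7.82-fold, Trpc5os at least 19.0-fold, Ptgds at least 8.58-fold, Ces1d at least 11.05-fold, Cd36 at least 6.67-fold and Tspan8 at least 4.93-fold lower, and log2 fold changes printed for these genes are fitted values, not bounds. Star, which delivers cholesterol to the mitochondrion, had a log2 fold change of -1.41 ± 0.16 (SE, adjusted p = 0.00927). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, had one of -1.79 ± 0.21 (adjusted p = 0.0106). Of 18 measured steroidogenesis genes, 4 fell, namely these 3 and the estrogen sulfotransferase Sult1e1, and 14 did not pass the test. Adjusted over the list alone, 9 were lower and 1 higher. As a group they were lower than other genes (median log2 fold change -0.28, camera adjusted p = 0.000249), with adjusted p = 0.717 with an estimated correlation. Cyp17a1 and Hsd17b3, later enzymes of testosterone synthesis, had log2 fold changes of -1.43 ± 0.42 (adjusted p = 0.133) and -1.95 ± 0.63 (adjusted p = 0.154), below their wild-type values on both knockout arrays but not past the test. The wild-type arrays differed in both genes: without wild-type replicate 1 the changes were -0.74 for Cyp17a1 and -0.82 for Hsd17b3, and without replicate 2 they were -2.13 and -3.07. Hsd3b1, a paralog named here after its values were seen, had a log2 fold change of 0.20 ± 0.43 (adjusted p = 0.788), and probe sets of such families can share signal between members.

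Of 21 measured adult Leydig cell markers, 8 fell and 13 did not pass the test, and adjusted over the list alone 13 were lower. Examples beyond Hsd3b6 were Sult1e1 (fitted log2 fold change -4.90 ± 0.81), the prostaglandin D synthase Ptgds (-4.49 ± 0.58) and the carboxylesterase Ces1d (-4.01 ± 0.23). The list had a median of -1.41 and was lower than other genes (camera adjusted p = 5.55e-13), with adjusted p = 0.616 with an estimated correlation. It shares 8 measured members with other lists, mostly those of steroidogenesis. Within the wild-type pair, replicate 2 had lower values of these markers than replicate 1, with a median difference of -0.54. Without wild-type replicate 1 the fitted change was -3.49 for Sult1e1 and -3.46 for Ptgds. Without replicate 2 it was -6.30 and -5.53. Markers of progenitor and fetal Leydig cells did not pass the group test (median 0.32, camera adjusted p = 0.266), but were called higher with the lowest 50% of genes left out (adjusted p = 0.00261). Their median was 0.18 without knockout replicate 1 and 0.54 without replicate 2. Of 16 measured, 3 rose and 2 fell. Thbs2, a matrix glycoprotein, and Sfrp1, a secreted Wnt modulator, rose (log2 fold changes 1.57 ± 0.18 and 1.55 ± 0.15), while Sult1e1 and Cyp11a1 fell. Genes of cholesterol synthesis and uptake, which feed steroid synthesis, counted 1 higher and 2 lower of 21 (camera adjusted p = 0.107, and 0.0225, lower, without wild-type replicate 2). The sterol enzymes Nsdhl and Tm7sf2 fell (-0.80 ± 0.11 and -0.68 ± 0.12), and Srebf2, a transcription factor of cholesterol synthesis, rose (0.72 ± 0.12).

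**Figure D1:**
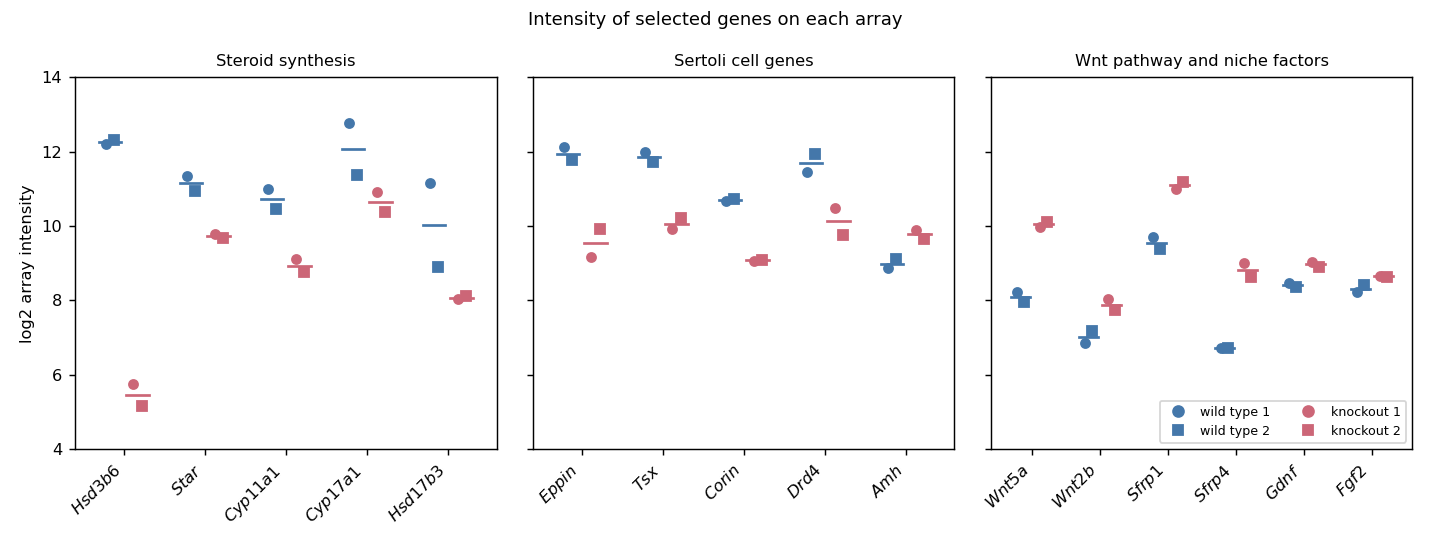
The plot gives the log2 array intensity (vertical axis) of selected genes (horizontal axis) in wild-type (blue) and knockout (red) testes, with circles for replicate 1, squares for replicate 2 and lines for the group means. Hsd3b6 lay between 12.21 and 12.32 in wild type and between 5.17 and 5.75 in the knockout, and Wnt5a between 7.95 and 8.24 in wild type and between 9.98 and 10.11 in the knockout; Cyp17a1, Hsd17b3, Gdnf and Fgf2 did not pass the test.

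Androgen-responsive genes of Sertoli cells, the cells that nurse germ cells, were lower in the knockout. Of 17 measured, 7 fell, none rose and 10 did not pass the test. Adjusted over the list alone, 10 were lower and 1 higher. Eppin, a secreted protease inhibitor, had a log2 fold change of -2.40 ± 0.25. Tsx, an X-linked gene of Sertoli cells, had one of -1.79 ± 0.16, the serine protease Corin one of -1.62 ± 0.11 and the dopamine receptor Drd4 one of -1.57 ± 0.26. The list median was -0.43 (camera adjusted p = 6.25e-06), with adjusted p = 0.616 with an estimated correlation. General Sertoli cell markers did not move as a group, with 1 of 29 higher, 1 lower and a camera adjusted p of 0.805. Amh, anti-Müllerian hormone, rose (0.80 ± 0.14, adjusted p = 0.0398), and Trf, transferrin, fell (-2.29 ± 0.24, adjusted p = 0.00746). The median of this list was 0.035, while its mean of -0.065 and its test pointed down. The receptor for follicle-stimulating hormone, Fshr, had a log2 fold change of 0.26 ± 0.14 (adjusted p = 0.289).

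Wnt5a (probe set 10413482) rose 3.86-fold in the knockout, with a 95% confidence interval of 3.07 to 4.86. Its mean was 10.05 ± 0.10 (SD, n = 2) against 8.10 ± 0.20 log2 intensity units in wild type, a log2 fold change of 1.95 ± 0.14 (SE, limma adjusted p = 0.00274). Wnt2b was the other ligand that rose (0.86 ± 0.16, adjusted p = 0.0434). The remaining 17 of 19 measured Wnt ligands did not pass the test, and the list as a whole did not either (median 0.18, camera adjusted p = 0.0763). It was called higher without knockout replicate 1 (median 0.32, adjusted p = 0.00925) and with the lowest 25% of genes left out (adjusted p = 0.0359), and had a median of 0.10 without knockout replicate 2. Adjusted over the list alone, 2 ligands were higher and 1 lower. Of 34 receptors and secreted modulators, 3 rose and 2 fell (camera adjusted p = 0.107, and 0.0263, higher, without wild-type replicate 2). The secreted modulators Sfrp4 and Sfrp1 rose (2.09 ± 0.15 and 1.55 ± 0.15). Porcn, the acyltransferase that Wnt secretion requires, and the receptor Fzd1 fell (-0.70 ± 0.12 and -0.64 ± 0.12). Among 17 target genes of Wnt beta-catenin signalling, Lef1 alone passed the test (0.70 ± 0.13, adjusted p = 0.0476; camera adjusted p of the list 0.429). Wnt2b and Fzd1 no longer passed after quantile normalization (adjusted p = 0.0637 and 0.0521), nor did Lef1 after each array was centred on its median (0.0513). Every gene called in this paragraph, Wnt5a included, no longer passed when some array was left out.

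Other factors known to act on spermatogonial stem cells did not move as a group, with none of 25 higher, 1 lower and a camera adjusted p of 0.805. Gdnf, the main self-renewal factor from somatic cells, had a log2 fold change of 0.55 ± 0.12 (adjusted p = 0.0684), higher on both knockout arrays but not past the test. It passed after quantile normalization (adjusted p = 0.0480). Fgf2 had a log2 fold change of 0.33 ± 0.12 (adjusted p = 0.188) and Csf1 one of -0.26 ± 0.15 (adjusted p = 0.328). Tgfb1, transforming growth factor beta 1, fell (-1.22 ± 0.11, adjusted p = 0.00551). Of 20 Notch pathway genes none passed the test (camera adjusted p = 0.623). The lowest p-values belonged to Hey2 (-0.64 ± 0.14, adjusted p = 0.0668) and Dll1 (0.28 ± 0.12, adjusted p = 0.236).

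Among the 10 largest rises, Ppp2r2c, a regulatory subunit of protein phosphatase 2A, had a log2 fold change of 2.78 ± 0.49, which was 1.93 without knockout replicate 2 and 3.63 without replicate 1. Acsl6, an acyl-CoA synthetase, followed with 2.37 ± 0.22, the proteoglycan Bcan with 2.19 ± 0.31 and the cerebellin Cbln3 with 2.17 ± 0.14. The plasma protein gene Ahsg (2.05 ± 0.16), the adhesion molecule Negr1 (1.96 ± 0.17), the ketone body enzyme Bdh1 (1.92 ± 0.16) and Shisa6 (1.82 ± 0.19) complete the set with Sfrp4 and Wnt5a. Among the 10 largest falls, Lcn2, an iron-siderophore carrier, had a log2 fold change of -4.71 ± 0.23 and Trpc5os a fitted one of -4.58 ± 0.14. The protease inhibitor Serpina3n (-3.95 ± 0.19), the homocysteine methyltransferase Bhmt (-3.91 ± 0.27), the water channel Aqp8 (-3.83 ± 0.28) and the fatty acid receptor Cd36 (fitted value -3.52 ± 0.33) followed. The other probe sets of Bhmt changed by -4.02 and -4.00. Serpina3n belongs to a family of near-identical genes, and its value is uncertain for that reason. Adjusted p-values of these genes lay between 0.000119 for Hsd3b6 and 0.0374 for Ppp2r2c.

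With all arrays, none of the germ cell lists passed the group test. Without wild-type replicate 1, the median was 0.28 for markers of differentiating spermatogonia and spermatocytes and 0.26 for those of spermatids. Without wild-type replicate 2 both medians were 0.09, and the test of the spermatid list pointed down. With the lowest 50% of genes left out, fewer than 5 markers of each list remained, as most were weakly expressed. The median log2 fold change of all genes was 0.07, and -0.04 with those left out. After quantile normalization the list medians were 0.04 and 0.05, against 0.18 for both before it. A change of these markers cannot be told from a general shift of weak genes, and equal germ cell content is not shown. Of 25 markers of undifferentiated spermatogonia, 2 fell and none rose (camera adjusted p = 0.965). These were Tspan8, a tetraspanin (fitted value -2.73 ± 0.18), and Etv5, a GDNF-responsive transcription factor that Sertoli cells also express (-1.07 ± 0.11). The list had a median of 0.11 and a mean of -0.11. Of 26 markers of differentiating spermatogonia and spermatocytes, Hspa2, a testis heat shock protein, fell (-0.87 ± 0.15; camera adjusted p of the list 0.204). None of 28 spermatid markers passed the test (camera adjusted p = 0.463). Those with the lowest p-values were Spaca1 (-0.69 ± 0.17, adjusted p = 0.0893) and Ropn1 (0.42 ± 0.11, adjusted p = 0.105), and the list had a median of 0.18 and a mean of -0.013. Of 23 retinoic acid pathway genes, the retinoic acid-forming enzyme Aldh1a2 and the alcohol dehydrogenase Adh1 fell (-1.72 ± 0.18 and -1.15 ± 0.16), and none rose. The camera adjusted p was 0.448, and the list had a median of 0.043 and a mean of -0.063.

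Macrophage markers were lower in the knockout testes. Of 24 measured, 7 fell, none rose and 17 did not pass the test, and adjusted over the list alone 18 were lower and 1 higher. Lyz2, lysozyme, had a log2 fold change of -1.55 ± 0.18, the folate receptor Folr2 one of -1.34 ± 0.12, the macrophage growth factor receptor Csf1r one of -1.02 ± 0.13 and the lysosomal protein Cd68 one of -0.95 ± 0.11. The list median was -0.83 (camera adjusted p = 2.74e-13), with adjusted p = 0.616 with an estimated correlation. Within the wild-type pair, replicate 2 had higher macrophage values than replicate 1, with a median difference of 0.29. With all arrays, the endothelial, peritubular and smooth muscle, lymphocyte and adipocyte lists did not pass the group test. Of 18 endothelial markers, the transcription factor Sox18 rose (1.02 ± 0.14), with a list median of -0.020, a mean of 0.014 and a camera adjusted p of 0.605. None of 16 peritubular myoid and smooth muscle markers passed (camera adjusted p = 0.859), the lowest p-values being those of Actg2 (-0.60 ± 0.13, adjusted p = 0.0693) and Myh11 (0.67 ± 0.17, adjusted p = 0.0971). None of 15 lymphocyte markers passed (camera adjusted p = 0.558), with Ighm at 0.39 ± 0.13 (adjusted p = 0.158) and Il2rb at 0.29 ± 0.12 (adjusted p = 0.209). A weaker probe set of Ighm had a change of -0.72. None of 13 adipocyte markers passed (camera adjusted p = 0.107), with Lpl at 0.65 ± 0.15 (adjusted p = 0.0730) and Plin1 at 0.57 ± 0.14 (adjusted p = 0.0861). Of 3 measured red blood cell genes, too few for a test of the list, the heme synthesis enzyme Alas2 fell (-2.66 ± 0.27).

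Markers of the epididymis and rete testis were high on a single array, wild-type replicate 2. Adam7, a gene of the epididymal epithelium, measured 11.04 log2 intensity units there and between 5.68 and 5.92 on the other 3 arrays. Rnase12 measured 10.27, Defb20 9.10 and Lcn5 8.91 on the same array. In all, 9 of the 18 measured markers were more than 1 log2 unit above all other arrays there. These examples were chosen after their values were seen. The list did not pass the group test (median -0.41, camera adjusted p = 0.239), but was called lower without wild-type replicate 1 (adjusted p = 2.29e-09) and not without replicate 2 (adjusted p = 0.530, pointing up). Epcam, an epithelial adhesion molecule, passed the test by itself (-2.06 ± 0.40, adjusted p = 0.0484), and its change was -1.36 without wild-type replicate 2 and -2.75 without replicate 1. Leaving out wild-type replicate 2 gave 197 genes higher and 451 lower, of which 122 and 327 were among those called with all arrays.

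**Figure D2:**
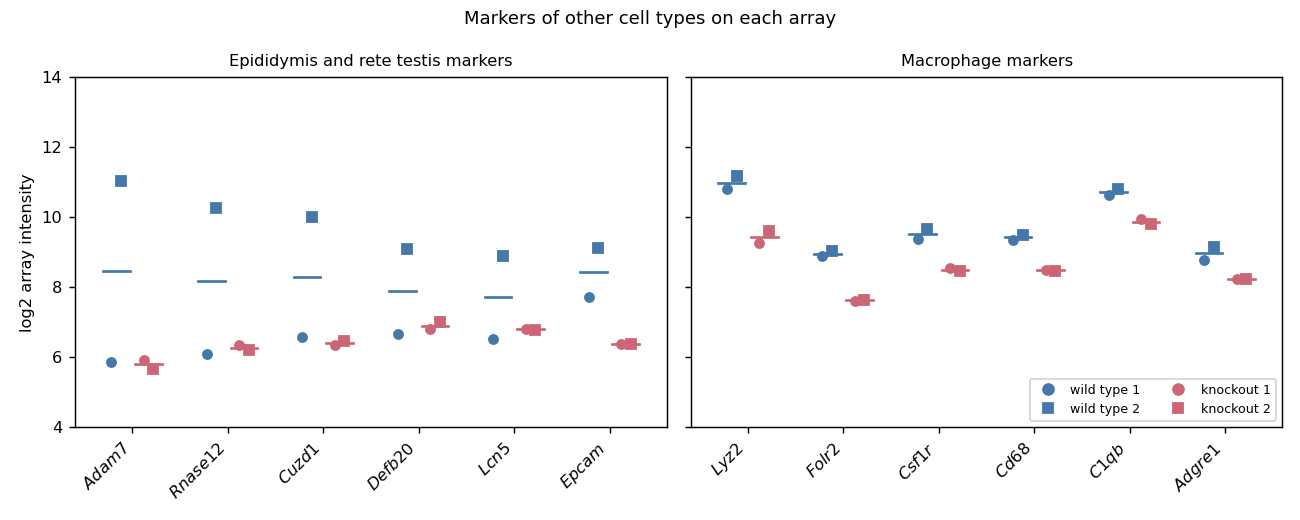
The plot gives the log2 array intensity (vertical axis) of markers of the epididymis and rete testis and of macrophages (horizontal axis) on each array, with symbols for the replicates and lines for the group means. Adam7 stood at 11.04 in wild-type replicate 2 and at or under 5.92 on the other arrays, whereas Lyz2, Folr2, Csf1r, Cd68, C1qb and Adgre1 were lower on both knockout arrays than on both wild-type arrays; C1qb and Adgre1 were chosen after their values were seen, and Adgre1 did not pass the test (adjusted p = 0.0615).

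Several general lists shifted by small amounts. Hormone receptors were higher as a group (median 0.26, camera adjusted p = 0.00563), with adjusted p = 0.751 with an estimated correlation, and without knockout replicate 1 they no longer passed (adjusted p = 0.0813). Of 18 measured, 3 rose, namely the PACAP receptor Adcyap1r1 (1.33 ± 0.13), the estrogen receptor Esr2 (0.85 ± 0.12) and the membrane receptor Gper1 (0.80 ± 0.14). Oxidative phosphorylation genes were lower as a group (median -0.15, camera adjusted p = 0.00212), with adjusted p = 0.616 with an estimated correlation and 0.0695 after quantile normalization. None of the 25 passed by itself, the lowest p-values being those of Ndufa1 (-0.62 ± 0.14, adjusted p = 0.0776) and Sdhb (-0.57 ± 0.13, adjusted p = 0.0847). Cell proliferation genes were lower as a group (median -0.15, camera adjusted p = 0.00309), with adjusted p = 0.717 with an estimated correlation and 0.187 without wild-type replicate 2. The mitotic kinase gene Cdk1 alone fell among the 24 (-0.97 ± 0.12). Immediate early genes were also lower (median -0.12, camera adjusted p = 0.00811), with adjusted p = 0.616 with an estimated correlation. Of 21, the phosphatase Dusp1 and the mRNA-decay factor Zfp36 fell (-0.89 ± 0.16 and -0.68 ± 0.13), the second not after quantile normalization (adjusted p = 0.0520). With the lowest 25% of genes left out, the proliferation and immediate early lists had an adjusted p of 0.0670. With the lowest 50% left out, the immediate early list had an adjusted p of 0.291 and the oxidative phosphorylation list one of 0.114.

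The remaining lists did not pass the group test with all arrays. Of 32 extracellular matrix genes, the collagens Col14a1 and Col15a1 rose (0.80 ± 0.13 and 0.78 ± 0.13) and the metalloproteinase inhibitor Timp1 fell (-2.51 ± 0.11; camera adjusted p of the list 0.623, and 0.0284, higher, with the lowest 50% of genes left out). None of 19 heat shock and unfolded protein response genes passed (camera adjusted p = 0.0881, and 0.0411, lower, with every probe set tested), with Sdf2l1 at -1.03 ± 0.22 (adjusted p = 0.0684) and Hspb1 at -0.67 ± 0.16 (adjusted p = 0.0839). None of 19 interferon response genes passed (camera adjusted p = 0.605), with Cxcl10 at -0.63 ± 0.13 (adjusted p = 0.0622) and Usp18 at -0.61 ± 0.13 (adjusted p = 0.0693). That list had a median of 0.076 and a mean of -0.014. None of 13 housekeeping genes passed (camera adjusted p = 0.107, and 0.0433, lower, without wild-type replicate 1), with Gusb at -0.48 ± 0.12 (adjusted p = 0.1002) and Hprt at -0.32 ± 0.14 (adjusted p = 0.229).

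**Figure D3:**
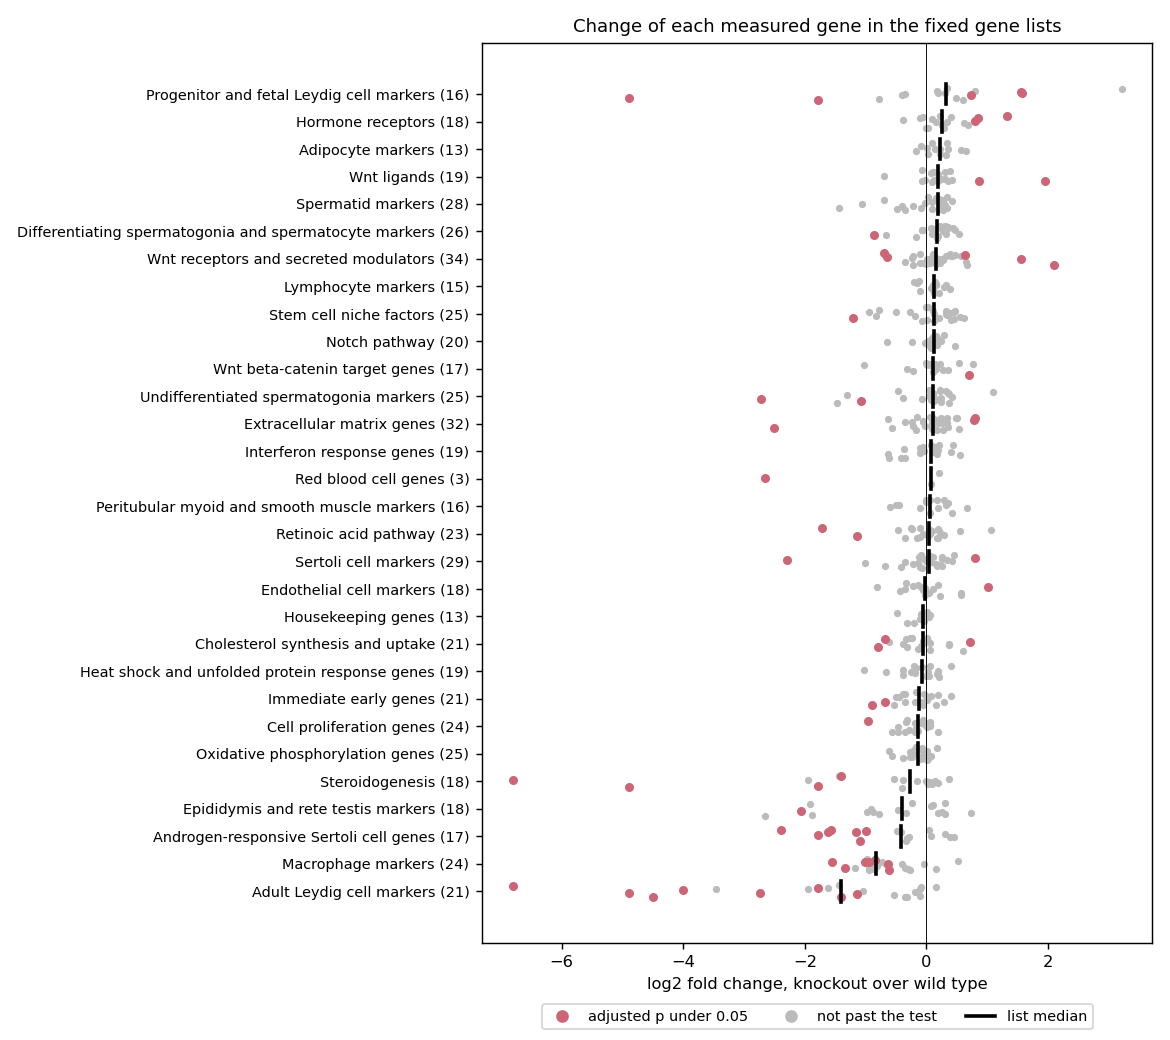
The plot gives the log2 fold change, knockout over wild type (horizontal axis), of each measured gene in the 30 gene lists (vertical axis, number of measured genes in parentheses), with red points for genes past the test, grey points for the others and black bars for list medians. The adult Leydig cell, macrophage and androgen-responsive Sertoli cell lists lie lowest, with medians of -1.41, -0.83 and -0.43.

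The groups of all 618 called genes did not overlap, which with 2 arrays per group follows from the selection and says nothing about stability. The calls rest on the estimate of spread that limma shares across genes, as an ordinary pooled-variance test called 0 genes after adjustment, with 1509 higher and 1290 lower at an unadjusted p under 0.05 against 2567 and 1949 with limma. Without knockout replicate 1 the counts were 2 higher and 16 lower, without knockout replicate 2 they were 2 and 21, and without wild-type replicate 1 they were 313 and 726, and 52 of the 59 named genes past the threshold no longer passed when some array was left out.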

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

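The result given here comes from a setting chosen before its values were seen, and no explanation was tested for it. Probe sets without a single gene symbol lie outside the gene comparison. When all 28856 probe sets were tested together with limma, 1 of these 7067 was higher in the knockout than in the wild-type controls and 5 were lower. The 1 higher probe set matches several genes and had a log2 fold change of 0.98 ± 0.11 (SE, adjusted p = 0.0487). Of the 5 lower ones, 2 match several genes and 3 have no gene listed, with log2 fold changes from -1.22 to -2.13.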

How the results depend on the processing

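Of the settings given here, only the further 32 added before the log2 step was chosen after seeing the data. With 192 genes higher and 426 lower in the knockout as the reference, quantile normalization, median centring, leaving out the lowest 25% or 50% of genes, averaging probe sets, eBayes with trend or a robust prior and the further 32 gave between 177 and 266 higher and between 409 and 540 lower. Testing every probe set gave 25 and 102 genes. Over the 136 probe sets called there, those without 1 gene included, 80.9% were lower, against 68.9% of the genes called in the reference. That setting adds 8918 probe sets, 7067 without 1 gene and 1851 of genes already tested, and the prior fell from 4.65 to 3.34 degrees of freedom. A change of at least 1 log2 unit left 64 and 213, and an adjusted p under 0.1 gave 482 and 762. The ordinary pooled-variance test gave 0 and 0, its smallest adjusted p being 0.143 with 2 residual degrees of freedom. Leaving out 1 array gave from 2 to 313 higher and from 16 to 726 lower. The low counts came without either knockout array (2 and 16, 2 and 21), when the spread rests on the wild-type pair and the remaining knockout array is assumed to vary like it. Without a wild-type array the spread rests on the knockout pair in the same way. Without wild-type replicate 1 they were 313 and 726, and without replicate 2 they were 197 and 451. No named gene or list called in the reference setting reversed.

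Of 59 named genes past the threshold, 7 stayed past it in every setting that tested them, except the ordinary test, which called no gene. These were Hsd3b6, Lcn2, Trpc5os, Ces1d, Serpina3n, Aqp8 and Timp1. With the lowest 50% of genes left out, 45 of the 59 stayed past it and the others were not tested. Of the 7, Trpc5os, Timp1 and Ces1d had means over the arrays under the array medians of 7.80 to 7.83 log2 units. They may therefore be among those not tested there, with Ces1d close to the limit. Of the 59, 52 did not stay past it when 1 array was left out and 32 did not in another setting, the ordinary test aside. For lists, 1 was higher and 7 lower. Higher lists numbered 2 with the lowest 25% of genes left out, 3 with the lowest 50% left out, from 1 to 3 without 1 array, and 0 with an estimated correlation and 0 with fry. Lower lists numbered 0 with an estimated correlation and 0 with fry, and from 5 to 9 elsewhere. The cause was not tested. An estimated correlation also missed the simulated list at this sample number, but its genes were simulated without correlation and fry was not run on it.

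Same-numbered arrays deviated from their group means with a correlation of 0.0205 over 2 pairs. With 2 arrays per group the second pair mirrors the first, so this value cannot settle whether same-numbered samples share more than a number. With the replicate block the counts were 173 higher and 399 lower, and 1 list higher and 7 lower. Signal over background was not given by detection calls, and weakly expressed genes near the lowest intensity of about 16 limit what can be seen.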

Other observations

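Among the tests below, those on array scaling for the Wnt genes, on genes near Lhcgr, on other acute-phase genes and on the second epididymal list were written before their results were seen, and the tests on macrophages, on stromal tissue and on array scaling for the epididymal markers were chosen, and in part reworded, after. The scaling test of the epididymal markers replaced an earlier one on their median, whose members went both ways. The acute-phase and second epididymal medians lay on the side written beforehand as speaking against their explanations, but within 1 SD of members that went both ways, and after they were seen they were read as leaving the explanations open.

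The wild-type testes also differed from each other in Leydig and spermatid genes, named here after their values were seen. Dlk1, a gene of fetal and progenitor Leydig cells, measured 10.82 log2 intensity units in wild-type replicate 1 and 6.53 in replicate 2, against 11.76 and 12.02 on the knockout arrays. Its log2 fold change of 3.21 ± 1.18 did not pass the test (adjusted p = 0.188). The sperm mitochondrial gene Smcp measured 9.06 in wild-type replicate 1 and 6.11 in replicate 2, and 6.12 and 6.18 in the knockout. Crisp2, a gene of late germ cells, measured 8.54 in wild-type replicate 1 and 6.998 in replicate 2, and 6.73 and 6.68 in the knockout. The median difference between the wild-type arrays over all 28 spermatid markers was -0.20, replicate 2 minus replicate 1. The knockout arrays differed in the spermatogonial genes Utf1 and Zbtb16, also named after their values were seen. Utf1 measured 9.69 in knockout replicate 1 and 7.33 in replicate 2, and Zbtb16 measured 8.38 and 6.73. Over all 25 markers of undifferentiated spermatogonia the median difference was 0.11, knockout replicate 2 minus replicate 1.

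Macrophage markers were lower in the knockout, with a median log2 fold change of -0.83 over 24 genes, none of which is in another list; the list had adjusted p = 0.616 with an estimated correlation. Endothelial markers, of another interstitial cell type, had a median of -0.020 (SD 0.42 over members), far above that of the macrophage markers. Adjusted over the endothelial list alone, 3 were higher and 2 lower. Adult Leydig cell markers, also interstitial, had a median of -1.41, with 20 of 21 below 0. The endothelial values argue against an equal fall of all interstitial cell types, but a loss of part of that tissue stays open. After quantile normalization the macrophage median was -0.77 (SD 0.47). Array medians already lay between 7.80 and 7.83 log2 units before that step. They leave little room for a difference in whole-array scaling, and the normalized median adds no separate test of it. RNA of another tissue in wild-type replicate 2 is argued against as the source of the whole fall by a median of -0.56 (SD 0.44) without that array. That median is smaller in size than -0.83, so a part of the fall from that array stays open. It remains open, and was not tested, whether fewer macrophages or lower expression in each may go with the genotype.

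Wnt5a, Sfrp1 and Sfrp4 were higher in the knockout, by log2 fold changes between 1.55 and 2.09. The extracellular matrix and peritubular lists together had a median of 0.093 (SD 0.50 over members), so they did not rise by a like amount. That median cannot decide whether the share of stromal tissue was larger, as the 3 genes stand among the largest rises overall or in their list. With the lowest 50% of genes left out, the extracellular matrix list was called higher (camera adjusted p = 0.0284) and the peritubular list was not (0.465). This explanation stays open. After quantile normalization the smallest of the 3 changes was 1.60 ± 0.16 (SE), with limma adjusted p-values of 0.00724 or less. Array medians already lay between 7.80 and 7.83 log2 units before that step, so it could hardly remove changes of this size. The close medians leave little room for a difference in whole-array scaling, and the normalized values add no separate test of it. The genotype could act on their expression or on the number of a cell type that expresses them, and these were not tested apart.

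Epididymal markers stood out in wild-type replicate 2. After quantile normalization, 5 of 18 markers were more than 2 log2 units above every other array, against 39 of 19920 other genes (Fisher's exact test, p = 3.47e-10). That p-value takes genes read on a single array as independent, though they may vary together, and does not measure the spread between samples. The count was 5 before normalization as well, so the test restates what had been seen and is no separate evidence against array scaling. Epididymal tissue collected with that testis is a candidate explanation that stays open: a second list of 19 measured genes had a median difference of 0.018 (SD 0.99) between the wild-type arrays, where Spink8 stood 3.77 and Defb42 1.86 above every other array and most members lay low on all 4 arrays. That median lies at the 98.2 percentile of 10000 random lists of the same size. Of the 426 genes called lower, 327 were also called without this array and 99 were not; how much its RNA adds to these calls stays open, and no biological explanation was tested.

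A hypothesis that DNA of the donor strain around the targeted allele accounts for the called genes was tested by gene order. Of the called genes with a known place, 0.810% lay within 100 gene positions of Lhcgr. As that window holds only 104 tested genes, the share had to be small and cannot decide the question. In the window, 5 of 104 genes were called, against 612 of 19815 elsewhere (Fisher's exact test, two-sided, p = 0.258). The odds ratio was 1.58, with a confidence interval of 0.50 to 3.84, which does not exclude an excess of calls near Lhcgr. Donor DNA reaching beyond the window was not tested, and the hypothesis stays open. The 5 genes, all lower, were Lbh, Ehd3, Galm, Epcam and Gm1976, named after their values were seen.

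Lcn2, Serpina3n and Timp1, which respond to inflammation, were among the genes that fell, and a lower acute-phase response could account for them. Of 24 other acute-phase genes, Lbp, C4b and Saa3 were called lower (log2 fold changes -1.94 ± 0.21, -0.94 ± 0.15 and -0.71 ± 0.13) and none higher, and these were named after their values were seen. The list had a median of 0.014 (SD 0.52) and a camera p of 0.127, or p = 0.233 with an estimated correlation. Members that went both ways keep this explanation open.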
